A study of Mus musculus with 10 samples.

How the data were processed

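Polyadenylated RNA from 10 neuroretinas was reverse transcribed with barcoded primers carrying unique molecular identifiers (UMIs) and template switching, amplified, made into libraries with a 10x Genomics kit and sequenced on a NovaSeq X Plus, per the labels' protocols. STAR and STARsolo are named with build GRCm39, per the submitters' processing notes; their versions, the annotation release, the counting settings, the use of strand and whether UMIs were collapsed are not given in the sources used here. If UMIs were not collapsed, counts include amplification copies and counting error is understated. The authors deposited 1 table of raw whole-number counts per Ensembl gene, 57186 genes by 10 libraries, of which 22756 had a count in any library. Libraries were matched to columns by the library name in the labels and to PBS or CNP by the treatment label.

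Gene symbols came from a table of Ensembl IDs, which matched 51880 IDs (21837 of those with a count); IDs without a symbol held 0.881% of all counts. Coordinates are not given, because the annotation at hand is GENCODE M21 on GRCm38 and the deposited counts were made on GRCm39. Where a symbol had several IDs, the one with the most counts was used for the gene lists. Before replicates were averaged, the 20 pairs of libraries within groups were compared by chi-square over genes: chi-square per degree of freedom ran from 4.4 to 36.5, so no pair was a duplicate within counting noise.

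Counts were filtered with filterByExpr at its defaults (minimum count 10, minimum total 15), which left 11499 genes, and scaled by TMM. The groups were compared with edgeR 4.0.16's quasi-likelihood test in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; no covariate was used, since the labels give no batch. Standard errors and 95% intervals follow from the quasi-likelihood F statistic. The common biological coefficient of variation was 19.1%. CPM values are scaled by TMM, and log2 CPM used a prior count of 2.

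For 37 gene lists fixed before the data were examined, camera of limma 3.58.1 was run on log2 CPM with a preset correlation of 0.01, adjusted over the 33 lists with at least 3 tested members, and again with an estimated correlation; fry was run beside it. It called 5 lists (2 higher, 3 lower) with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.683); fry called 0. Each list also got a score per library, the mean log2 CPM of its tested members, whose difference is the difference between group means of log2 CPM, compared over all 252 assignments of 5 and 5 libraries. The smallest two-sided p of that exact permutation test is 0.00794. Means, medians and sign counts of list members are of the edgeR log2 fold changes, which can differ from the score difference where libraries spread widely. The permutation test called 0 lists after adjustment, and 2 had an unadjusted p under 0.05. Library measures were tested in the same way. The 4 lists with fewer tested members (horizontal cell, other leukocytes, fibroblast and sclera, skeletal muscle) are given as summed CPM on library totals. Correlations over the 10 libraries used 100000 permutations.

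The rule for named genes was fixed before the data were examined. It takes the 12 genes higher and 12 lower with the smallest p among those past the threshold; up to 4 members of each list past the threshold; of a list with none past it, up to 2 members with the highest mean expression; if fewer than 10 genes pass in all, the 5 higher and 5 lower with the smallest p; and a few marker genes always, among them Gfap, Aif1 and Hmox1. Some single genes that the rule names are not reported here. Gene models without an assigned symbol were counted and not named. Since no gene passed, the first parts of the rule named none. H2-Aa, Cd74, Gpnmb, Cd68, Acta1 and Xist were added after their values were seen, as were other single list members named where they set a list's mean or sum.

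The scripts were tested on simulated negative binomial counts for the same 11499 genes, with 50 genes changed at each fold: 28% of 1.5-fold, 68% of 2-fold, 92% of 3-fold and 100% of 4-fold changes were recovered, with 8 false calls. Folds were also put into the deposited counts by binomial thinning in 5 draws, with 250 genes per fold over all draws. Genes at every fold were changed together, which eases the adjusted threshold for each. In the same order of folds, 28.8%, 64.4%, 88.8% and 96% were recovered, with 0 false calls in any draw. In simulated counts drawn independently for each gene, a list raised 1.5-fold was called by camera, and 0 of 32 others were. Genes of a list vary together in the deposited counts (estimated correlation 0.973 for crystallins). The simulation therefore does not measure how often camera calls unchanged lists there.

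Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, robust dispersions, DESeq2 size factors, upper-quartile scaling and totals only in place of TMM, no low-count filter, a mean CPM of at least 5, removal of mitochondrial genes, a log2 fold threshold of 1, a surrogate variable from sva 3.50.0, camera with an estimated correlation, fry, a prior count of 0.5 and leaving out each library in turn. Added after seeing the data were log2 total count as a covariate, the surrogate variable and the pigment epithelium score as covariates of the list tests, the phagocyte list without Lyz2, and, as a covariate of the gene and list tests, whether the library number in the labels was above 10. Relations within the sets of libraries numbered up to 10 and above 10 used all 14400 orders of libraries within sets.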

Results

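Transcript abundance was measured by bulk RNA sequencing in mouse neuroretina, the light-sensing neural tissue at the back of the eye, 14 days after an injection into the vitreous, the gel in front of the retina. The injected material was graphitic carbon nitride nanoparticles (CNP), a polymer of carbon and nitrogen, given as 1 µL at 1 mg/mL in phosphate-buffered saline (PBS). The comparison group received PBS alone, so that the effect of the injection itself is shared by both groups. Each group held 5 libraries from female C57BL6/JRj mice, named here by group and the number in the labels. The design text speaks of 5 mice for CNP and of 5 eyes for PBS. The labels do not state beyond this whether each library came from a separate animal. The p-values of the gene tests and permutation tests measure the spread between these libraries. Camera with a preset correlation compares the genes of a list with other genes, so its p-values rest mainly on the spread between genes.

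The total counts of the PBS libraries were 5428697 for PBS 2, 5335892 for PBS 6, 4325794 for PBS 10, 3919337 for PBS 14 and 3328518 for PBS 18. Those of the CNP libraries were 5354649 for CNP 4, 4582313 for CNP 8, 3493667 for CNP 12, 4337612 for CNP 16 and 4210933 for CNP 20. A count of 0 in 1 library therefore allowed an abundance of up to 0.553 CPM (counts scaled to a common library total) in the deepest library and 0.901 CPM in the shallowest, which covers counting error only, as do all such limits here. The mean total was 4468000 ± 907700 in PBS and 4396000 ± 671900 in CNP (SD, n = 5 each; exact permutation p = 0.929, two-sided). The share of counts in mitochondrially encoded genes was 2.94% ± 1.28 in PBS and 2.94% ± 0.673 in CNP (SD, n = 5 each; exact permutation p = 1). This share includes mitochondrial ribosomal RNA (1.54% of counts in PBS and 1.45% in CNP), and 5 mitochondrial genes had 0 counts in every library. None of the 10 library measures compared differed between the groups after adjustment.

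The first question of the design is whether the nanoparticles changed the retinal transcriptome relative to PBS. Of 11499 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 were lower in CNP at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 137 genes, 67 higher and 70 lower. Evenly spread p-values would give 575. Other divisions of the libraries into equal groups gave a median of 311, and 12 of them had 137 or fewer. A count below 575 is therefore not particular to the treatment, and its cause was not tested. DESeq2, run on 22747 genes without the low-count filter, called 0 genes, with 146 at an unadjusted p under 0.05. On the 11499 filtered genes limma-voom also called 0, with 142. The 95% interval of the fold change lay within 2-fold in either direction for 10832 genes (94.2%) and within 1.5-fold for 7505 (65.3%). Groups did not overlap for 33 genes (0.287%), where chance gives 0.794%. Known fold changes were put into the deposited counts of many genes at once. Among genes at 20 CPM or more, the test recovered 88.2% of 2-fold and 48.9% of 1.5-fold changes. Below 20 CPM it recovered 39.8% of 2-fold, 79.8% of 3-fold and 92.4% of 4-fold changes. Smaller changes, and changes of scarce transcripts, were therefore often not detectable at this depth and number of libraries. If only a few genes changed, the adjusted threshold would be stricter and a smaller share would be recovered.

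**Figure D1:**
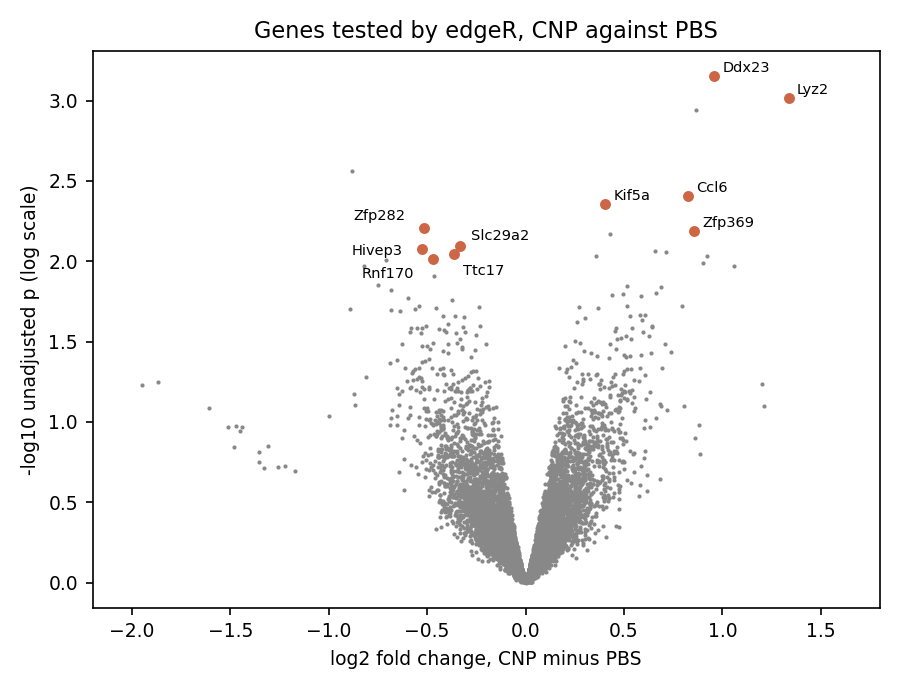
Each point is 1 of the 11499 tested genes, with its log2 fold change (CNP minus PBS) on the x axis and the negative log10 of its unadjusted edgeR p on the y axis; orange points are the 5 higher and 5 lower genes with the smallest p among those with an assigned symbol. Lyz2 (1.34) and Ddx23 (0.96) lie at the upper right, and no gene passed the adjusted threshold.

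The genes with the smallest p are given as values, since none passed (smallest edgeR adjusted p = 0.9997). Ddx23 (ENSMUSG00000003360), a helicase of the spliceosome, had a log2 fold change of 0.96 (SE 0.22), from 14.1 ± 2.70 to 27.0 ± 8.19 CPM (SD, n = 5 each). Lyz2 (ENSMUSG00000069516), the lysozyme of macrophages and neutrophils, had 1.34 (SE 0.31), from 3.77 ± 1.06 to 9.23 ± 3.67 CPM, and all 5 CNP libraries exceeded the PBS mean, although CNP 8 at 4.02 CPM lay below PBS 14 (5.13 CPM) and PBS 18 (4.55 CPM). Its 95% interval ran from 0.66 to 2.02. Its close relative Lyz1 had 2 counts in PBS and 2 in CNP, while Lyz2 had 80 and 200; how reads shared by the pair were counted is not given in the sources used here. Ccl6 (ENSMUSG00000018927), a chemokine of myeloid cells, had 0.83 (SE 0.24), from 2.05 to 3.61 CPM, with no overlap between the groups. Kif5a (ENSMUSG00000074657), a neuronal kinesin motor, had 0.41 (SE 0.12), and the zinc finger gene Zfp369 (ENSMUSG00000021514) 0.86 (SE 0.26), with PBS 14 at 1.21 CPM below its 4 companions. On the lower side were Zfp282 (ENSMUSG00000025821; -0.51), the nucleoside transporter Slc29a2 (ENSMUSG00000024891; -0.33), Hivep3 (ENSMUSG00000028634; -0.53), Ttc17 (ENSMUSG00000027194; -0.36) and Rnf170 (ENSMUSG00000013878; -0.47). For Ttc17, PBS 6 stood at 36.7 CPM and the rest of that group at 29.3 to 30.3 CPM. Like Ccl6, the genes Zfp369, Hivep3, Ttc17 and Rnf170 showed no overlap between the groups, and all of these were picked for a small p.

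**Figure D2:**
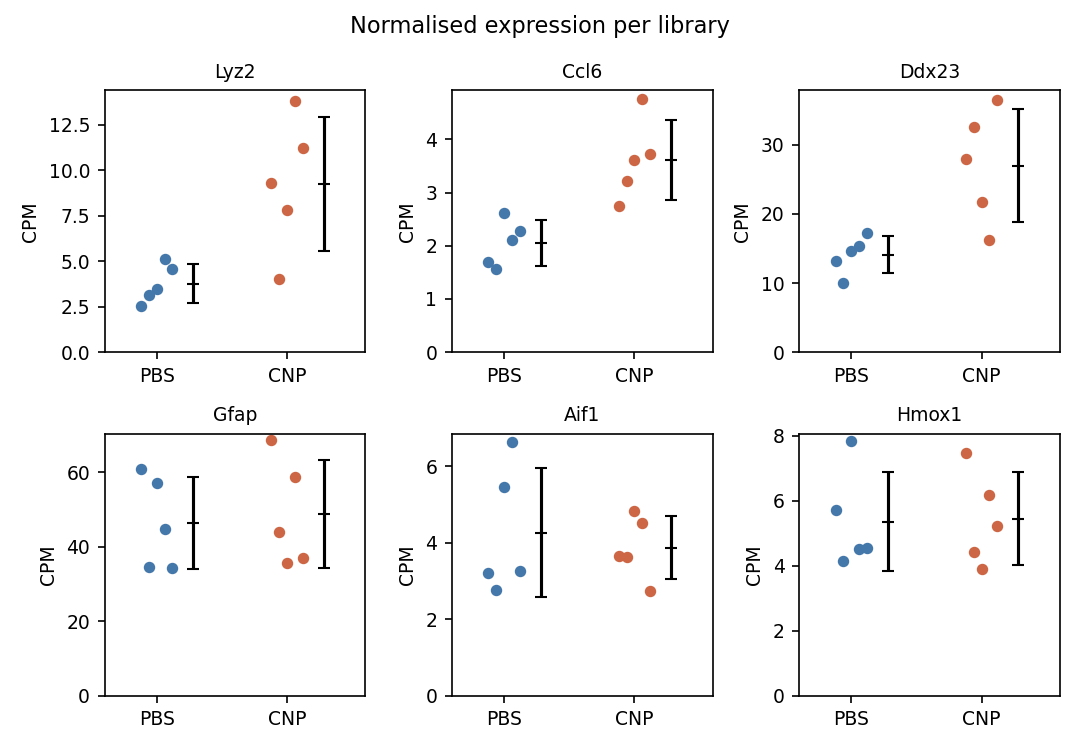
CPM of 6 genes in each library (y axes, starting at 0), with PBS in blue and CNP in orange; black marks give the mean ± SD of 5 libraries. Lyz2 averaged 3.77 CPM in PBS and 9.23 in CNP and overlapped between the groups through CNP 8 (4.02 CPM). Ddx23, Gfap, Aif1 and Hmox1 also overlapped, through other libraries in the case of Ddx23, while Ccl6 (2.05 and 3.61) did not.

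No list of retinal neuron genes passed the list test with all 10 libraries. Of 24 rod photoreceptor genes, 10 had a positive and 14 a negative fold change, with a mean log2 fold change of -0.017 and a median of -0.018, while the score, a mean of log2 CPM, differed by 0.0057. The transducin subunit Gnb1 had a log2 fold change of -0.13 (95% interval -0.61 to 0.35). Among 11 cone genes the mean was -0.03, with the short-wavelength cone opsin Opn1sw at -0.02. The 11 bipolar cell genes averaged -0.08, with Gng13 at 0.09 and Pcp2 at 0.02. Of 11 amacrine genes 10 were negative, with a mean of -0.21 and a median of -0.15 (score difference -0.09, exact permutation p = 0.802), with Calb2 at 0.02 and the glycine transporter Slc6a9 at -0.29. Of 14 ganglion cell genes, 12 were positive, with a mean of 0.06; the neurofilament gene Nefl had 0.11 and Sncg 0.08. The 20 synaptic genes averaged -0.10, with Snap25 at -0.04 and Cplx4 at 0.08; CNP 4 held 1830 CPM of Snap25 and the other CNP libraries 1400 to 1470. Horizontal cell genes, too few after filtering for a list test, summed to 294 ± 105 CPM in PBS and 297 ± 76.4 in CNP (SD, n = 5 each; exact permutation p = 0.952). Calb1 held 6750 of the 6862 counts in PBS and 6583 of the 6679 in CNP, so the sum speaks almost only for that gene. Camera with the preset correlation called ganglion cell genes higher without PBS 2 (adjusted p = 0.0405) or CNP 20 (0.0286), and without PBS 14 it called rod genes higher (0.035) and amacrine genes lower (0.00323). With an estimated correlation these calls ended (adjusted p = 0.923 without PBS 2, 0.903 without CNP 20 and 0.904 for both lists without PBS 14). With the pigment epithelium score as a covariate, added after seeing the data, rod genes were called lower (adjusted p = 2.95e-06) and amacrine genes higher (0.000813). Both directions were opposite to those without PBS 14. With all 10 libraries and no covariate, camera's direction was lower for both lists, and neither was called. Cone genes, not called elsewhere, were called lower with that covariate (0.0261). Ganglion cell genes were called higher with that covariate (2.95e-06) and with 1 surrogate variable (0.000541). With an estimated correlation, adjusted p was 0.586 for each of the 4 lists with that covariate and 0.717 for ganglion cell genes with the surrogate variable. With library number above 10 as a covariate, also added after seeing the data, rod genes were called lower (0.00142) and ganglion cell genes higher (2.4e-05), but adjusted p = 0.822 for both with an estimated correlation.

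No list of glial genes passed with all 10 libraries. The 11 Müller glia genes had a mean of 0.03 and a median of -0.022, with glutamine synthetase (Glul) at 0.08 and Clu at -0.02. Of 15 reactive gliosis genes, 8 were positive and 7 negative, with a mean of -0.004 and a median of 0.0038. Gfap (ENSMUSG00000020932), the intermediate filament gene used as the standard marker of retinal gliosis, measured 46.3 ± 12.4 CPM in PBS and 48.8 ± 14.4 in CNP (SD, n = 5 each). Its log2 fold change was 0.08 with a 95% interval of -0.39 to 0.54, which leaves out a 2-fold change in either direction. S100a6 had 0.10 and Stat3 -0.06. The 4 astrocyte genes averaged 0.01, with S100b at 0.10. Without PBS 2, camera called Müller glia genes higher (adjusted p = 0.0405), and so it did with the pigment epithelium score as a covariate (0.00783); adjusted p was 0.923 and 0.586 with an estimated correlation.

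Genes of activated phagocytes leaned towards CNP, on low counts. Of 18 fixed members 11 could be tested; 9 were positive and 2 negative, with a mean log2 fold change of 0.38 and a median of 0.19. Beside Lyz2, the members with the largest positive values, chosen after their values were seen, were the antigen presentation genes H2-Aa (0.92) and Cd74 (0.81), then Gpnmb (0.64) and the lysosomal membrane gene Cd68 (0.50). Each of these averaged under 10 CPM in both groups. Other antigen presentation genes of the list showed less: H2-Ab1 had 0.19, and H2-Eb1, which was not tested, had 34 counts in PBS and 36 in CNP. The members Cd63 (0.06) and Spp1 (0.09), which other retinal cells also express, were the most abundant, and the lipase Lpl had -0.49. By edgeR 0 members passed over all genes, and 1 (Lyz2, adjusted p = 0.0106) adjusted over the list alone. The limma camera test with a preset correlation called the list (adjusted p = 0.000112), but adjusted p = 0.683 with an estimated correlation, and fry gave an adjusted p of 0.786. With the library as the unit, the list score was 3.302 ± 0.167 in PBS and 3.66 ± 0.247 in CNP (SD, n = 5 each; exact permutation p = 0.0317, 0.523 adjusted over 33 lists). The score difference was 0.34 among the 5 libraries with the larger totals and 0.26 among the other 5 (exact permutation p = 0.2 in each, where 0.1 is the smallest possible). It was 0.37 among the 5 libraries numbered up to 10 and 0.40 among the 5 numbered above 10 (exact permutation p = 0.1 and 0.2, where 0.1 is again the smallest possible). The mean of these differences was 0.382 (exact permutation p = 0.02 over 100 assignments within the sets, not adjusted over lists). With library number above 10 as a covariate, camera's adjusted p was 0.000105, but adjusted p = 0.822 with an estimated correlation (0.0342 unadjusted).

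**Figure D3:**
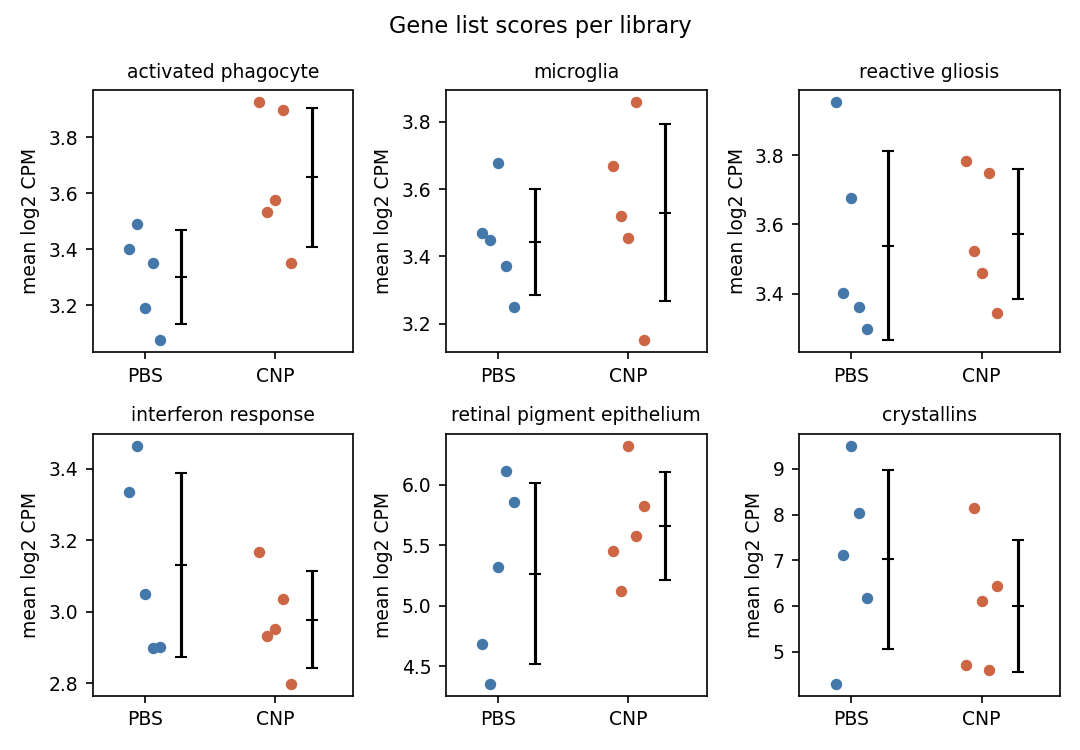
Mean log2 CPM of 6 gene lists in each library (y axes, not starting at 0), PBS in blue and CNP in orange, with black marks for the mean ± SD of 5 libraries. The activated phagocyte score averaged 3.302 in PBS and 3.66 in CNP, the crystallin score spread widely within both groups, and no score passed adjustment over 33 lists.

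Markers of resident microglia gave smaller values. The 12 microglia genes averaged 0.09, with 9 positive (exact permutation p = 0.556 for the score). Aif1 (ENSMUSG00000024397), which encodes the marker IBA1, had a log2 fold change of -0.11 (95% interval -0.71 to 0.48), and Ctss 0.20. Without CNP 20, camera called the list higher (adjusted p = 0.00491), but adjusted p = 0.903 with an estimated correlation. Markers of other leukocytes summed to 24 counts in PBS and 35 in CNP, too few for a list test (exact permutation p = 0.143). Of 25 cytokine and NF-kB genes 5 could be tested, with a mean of -0.04; Nfkbia had -0.01 and Vcam1 0.13. Tnf, Il1b, Il6, Cxcl1 and Cxcl2 had 0 counts in all 10 libraries, which allows up to 0.0677 CPM over the pooled counts. The score of this list was 3.88 in PBS 6 and 3.36 to 3.49 in the other PBS libraries. The 12 complement and class I genes had a mean of -0.03 and a median of -0.05 but a score difference of 0.01, with Tapbp at -0.01 and H2-D1 at -0.09.

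Interferon response genes leaned the other way. Of 18 tested genes 16 were negative, with a mean of -0.21, and 0 passed over all genes or adjusted over the list alone. Ifit3, an interferon-induced gene, had -0.24. Camera with a preset correlation called the list (adjusted p = 0.00355), but adjusted p = 0.983 with an estimated correlation, and the score did not separate the groups (exact permutation p = 0.31). The preset call ended without PBS 6 (adjusted p = 0.219), without CNP 8 (0.0591) or without CNP 20 (0.06), and with the pigment epithelium score (0.307) or library number above 10 (0.0599) as a covariate. The score difference was -0.35 among the 5 libraries with the larger totals and -0.07 among the other 5, and -0.23 among the 5 libraries numbered up to 10 and 0.03 among those above.

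No list of stress or metabolic genes passed with all 10 libraries. The 21 oxidative stress genes averaged 0.04, with the ferritin genes Ftl1 at -0.02 and Fth1 at 0.0011. Hmox1 (ENSMUSG00000005413), which encodes heme oxygenase 1, had 0.03 (95% interval -0.48 to 0.54). The 17 genes of p53 and apoptosis averaged 0.07, with Bax at 0.21 and Bcl2l1 at 0.02. Means were -0.04 for 16 unfolded protein response genes, where Hsp90b1 had 0.04 and Hspa5 -0.07, and -0.03 for 10 heat shock genes (median 0.02, score difference 0.01), where Hspa8 had -0.17 and Hsp90ab1 -0.0059. The 22 lysosome and autophagy genes had a mean of -0.01 and a median of 0.0023, with Ctsb at 0.07 and Map1lc3b at 0.14. The 17 hypoxia and glycolysis genes averaged -0.0045, with Aldoa at -0.03 and Eno1 at -0.12. The 26 nuclear genes of oxidative phosphorylation averaged 0.02, with Ndufa4 at 0.08 and Atp5b at -0.07. The 8 mitochondrially encoded genes averaged 0.17 with a median of 0.07; without mt-Nd6 (0.86) the mean was 0.07, and the score difference over all 8 was 0.28 (exact permutation p = 0.5). Of the abundant members, mt-Nd1 had 0.09 and mt-Cytb 0.0032. The 21 ribosomal protein genes averaged 0.03, with Rps14 at -0.05 and Rps18 at -0.02. Camera called mitochondrially encoded and ribosomal protein genes higher without CNP 8 (adjusted p = 0.0163 and 0.00624), PBS 14 (0.00155 and 0.00063) or PBS 18 (0.00356 and 0.000797), and oxidative phosphorylation genes without PBS 14 (0.00594). With an estimated correlation adjusted p was 0.982 without CNP 8, 0.904 without PBS 14 and 0.924 without PBS 18 for each of these lists. Mitochondrially encoded genes were also called higher with log2 total count as a covariate (0.0473), but adjusted p = 0.977 with an estimated correlation. With the pigment epithelium score as a covariate, ribosomal protein (6.1e-05) and oxidative phosphorylation genes (0.00852) were called lower, but adjusted p = 0.586 and 0.649 with an estimated correlation. The 16 clock genes averaged -0.07, with Bhlhe41 at -0.32 and Dbp at -0.0032. The 12 immediate early genes averaged -0.06, with Btg2 at -0.04 and Egr1 at -0.03; Egr1 stood at 353 CPM in PBS 2 and 314 CPM in CNP 4, and at 130 to 166 CPM elsewhere. Across the 28 lists that camera did not call with all libraries, adjusted p ranged from 0.21 to 0.96.

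Lens transcripts varied widely between libraries, with a standard deviation of the crystallin score of 1.96 in PBS and 1.45 in CNP. All 12 tested crystallin genes, which encode the structural proteins of the lens, were negative, with a mean of -1.32 and a median of -1.35, and the score differed by -1.03. Cryaa averaged 1250 ± 1224 CPM in PBS and 555 ± 677 in CNP, and Crybb2 1072 ± 1126 and 433 ± 450 (SD, n = 5 each). The 6 lens genes, some of them crystallins, averaged -1.50, with Crygs at -1.35, and their score differed by -1.03. Camera called both lists lower (adjusted p = 0.000112 and 0.00859), but adjusted p = 0.983 with an estimated correlation for each, and both scores gave an exact permutation p of 0.373. Without PBS 10 the preset adjusted p was 0.168 for crystallins, and for lens it was 0.395 without PBS 10, 0.151 without CNP 4, 0.175 without PBS 14, 0.223 without CNP 16 and 0.0529 with library number above 10 as a covariate. Among the 5 libraries with larger totals the crystallin score difference turned to 0.11 and the lens one to 0.22, against -1.64 and -1.74 among the other 5. Among the 5 libraries numbered up to 10 these differences were -0.55 and -0.50, and among those above -1.39 and -1.42. The crystallin score followed 3 other lens genes over the 10 libraries (Pearson r = 0.989, Spearman rho = 0.988, permutation p = 1e-05 for each, the smallest that 100000 resamples can give, adjusted 4e-05 over 4 relations; r = 0.994 without the 2 farthest libraries).

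Genes of the retinal pigment epithelium, the layer behind the photoreceptors, had a mean of 0.30 and a median of 0.38 over 10 members, 9 of them positive, and the score differed by 0.40. Ttr had 0.36 (565 ± 362 CPM in PBS and 722 ± 273 in CNP, SD, n = 5 each) and Rlbp1, which Müller glia also express, 0.12. Camera called the list higher (adjusted p = 0.00268), but adjusted p = 0.983 with an estimated correlation, and the score gave an exact permutation p of 0.333. The preset call ended without PBS 2 (0.0864), PBS 6 (0.378) or CNP 12 (0.154), and with library number above 10 as a covariate (0.097). The score difference was 0.87 among the 5 libraries with the larger totals and 0.31 among the other 5, and 0.50 among the 5 libraries numbered up to 10 and -0.08 among those above. The 4 pigment cell genes averaged 0.17, with Dct at 0.32 and Tyrp1 at -0.44. The 9 endothelial genes averaged 0.10, with Esam at 0.03 and Kdr at -0.10, and camera called them higher without CNP 20 (adjusted p = 0.0287), but adjusted p = 0.903 with an estimated correlation. The 3 pericyte and smooth muscle genes were all positive, with Rgs5 at 0.08 and Acta2 at 0.24. Their score was 3.49 ± 0.0924 in PBS and 3.67 ± 0.0928 in CNP (SD, n = 5 each; exact permutation p = 0.0238, 0.523 adjusted), and camera gave an adjusted p of 0.348. For Rgs5, PBS 6 stood at 29.1 CPM and the rest of that group at 38.7 to 42.7. The 4 hemoglobin and erythrocyte genes had a mean of 0.01, a median of -0.08 and a score difference of -0.0079, with Hbb-bs at -0.08 and Hba-a1 at -0.09, whose near-identical copies leave the split of reads uncertain. The 3 corneal and ciliary genes averaged -0.09, with Aqp1 at 0.01 and Aqp5 at -0.19. Fibroblast genes summed to 15.3 ± 4.85 and 16.4 ± 7.78 CPM (exact permutation p = 0.817), and skeletal muscle genes to 39.2 ± 5.15 and 68.3 ± 59.6 CPM in PBS and CNP (SD, n = 5 each; exact permutation p = 0.278). That CNP mean rested on CNP 12 at 174 CPM: without it the mean was 41.8 ± 6.78 CPM (SD, n = 4; exact permutation p = 0.556).

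The first principal component of log2 CPM, with 44.6% of the variance, followed the total count rather than the treatment (Pearson r = -0.858 with log2 total, permutation p = 0.00173, adjusted 0.00231; Spearman rho = -0.903, permutation p = 0.00074, adjusted 0.000987 over 4 relations). Without the 2 libraries farthest from the median total, r was -0.847. Either group alone held 5 libraries, too few for a coefficient of its own. The component also parted the libraries by the number in the labels, which do not say what it marks: it ran from -32.6 to -6.33 in the 5 numbered up to 10 and from 11 to 38.2 in the 5 above (exact permutation p = 0.00794, the smallest possible), a grouping noticed after seeing the data. These sets held 3 PBS and 2 CNP libraries, and 2 PBS and 3 CNP, with mean totals of 5005000 and 3858000 (exact permutation p = 0.0159 for log2 total). With the mean of each set taken off, the relation to the total no longer passed (r = -0.527, exact permutation p = 0.146; rho on ranks within sets = -0.65, exact permutation p = 0.0761; 10 libraries). The component averaged -2.11 ± 30.8 in PBS and 2.11 ± 19.6 in CNP (SD, n = 5 each; exact permutation p = 0.81). The pigment epithelium score followed the same component (r = 0.911, rho = 0.964, permutation p = 0.00024 and 8e-05, adjusted 0.00048 and 0.00016; r = 0.89 without the 2 farthest libraries), and within the sets by number r was 0.712 and rho 0.85 (exact permutation p = 0.0342 and 0.00931).

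**Figure D4:**
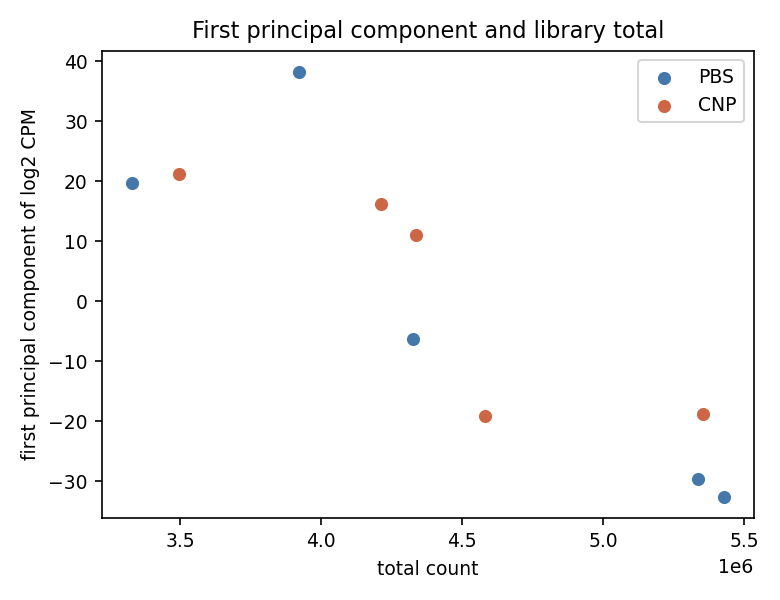
First principal component of log2 CPM (y axis) against total count (x axis) for 10 libraries, PBS in blue and CNP in orange. The component falls as the total rises (r = -0.858 with log2 total), and both groups span it; libraries numbered up to 10 lie below 0 and those above 10 lie above 0.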

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

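Over 84 named genes, 33 list scores and 10 library measures, 254 groups of 5 libraries were searched for a library whose gap to its nearest neighbour took up most of the group's range. This found 10, and chance gives about 1 in 20 groups (12.7 here), so their number is no more than chance gives. H2-Aa, Cd74, Gpnmb, Cd68, Acta1 and Xist were chosen after their values were seen.

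In PBS, the cytokine and NF-kB score was high in PBS 6 (3.88, others 3.36 to 3.49). Zfp369 was low in PBS 14 (1.21 CPM, others 2.36 to 2.6) and Ttc17 high in PBS 6 (36.7 CPM, others 29.3 to 30.3). Pcp2 was high in PBS 14 (1010 CPM, others 956 to 969), Egr1 high in PBS 2 (353 CPM, others 130 to 166) and Rgs5 low in PBS 6 (29.1 CPM, others 38.7 to 42.7). In CNP, the immediate early gene score was high in CNP 4 (5.71, others 5.06 to 5.14), with Egr1 at 314 CPM (others 132 to 164) and Snap25 at 1830 CPM (others 1400 to 1470) in the same library. Acta1, the actin of skeletal muscle, was high in CNP 12 (58.7 CPM, others 6.91 to 8.84).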

How the results depend on the processing

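No paired analysis was possible because the groups share no replicate number and the labels give no pairing. The covariates of total count, library number and pigment epithelium score, the surrogate variable in the list tests and the list without Lyz2 were chosen after seeing the data. The count of 0 genes higher and 0 lower held under all 13 other settings and with each library left out, while genes at an unadjusted p under 0.05 numbered 137 in edgeR, 370 with a surrogate variable, 240 with the total and 272 with library number above 10 as a covariate, 422 without a filter and 117 to 301 with a library left out; the cause was not tested. Lyz2 came nearest without CNP 8 (adjusted p = 0.481, highest 1). The 2 higher and 3 lower lists became 0 and 0 with an estimated correlation and with fry, and 4 and 6 with the pigment epithelium score as a covariate. With an estimated correlation and with fry, adjusted p was 0.683 and 0.786 for activated phagocytes, and 0.983 and 0.999 for interferon response, crystallins, pigment epithelium and lens; a larger correlation widens camera's spread by construction. Interferon response had 0.307 with the pigment epithelium score; with library number it had 0.0599, pigment epithelium 0.097 and lens 0.0529, where the score differences went from -0.15, 0.40 and -1.03 to -0.10, 0.21 and -0.96 (the cause was not tested). Of 25 calls that only alternatives gave to other lists, 0 passed with an estimated correlation (smallest adjusted p = 0.586). With a library left out, higher lists numbered 1 to 6 (6 without PBS 14, 5 without CNP 20, 4 without CNP 8 or PBS 18, 1 without PBS 6 or CNP 12) and lower lists 1 to 3 (1 without PBS 10). Adjusted p then ranged from 3.23e-07 to 0.0259 for phagocytes, 6.91e-15 to 0.168 for crystallins, 0.000864 to 0.219 for interferon, 8.27e-05 to 0.378 for pigment epithelium and 8.12e-09 to 0.395 for lens; the cause was not tested. The phagocyte score's exact permutation p was 0.00794 (without CNP 20) to 0.0714 (without PBS 18) and 0.0635 with totals only. Of 1840 fold changes of named genes under alternatives, 163 changed sign, 0 past the threshold; of 396 list score differences 67 did; 0 of 90 library measures passed. At this depth, with many genes changed together, 88.2% of 2-fold changes were recovered at 20 CPM or more and 39.8% below it.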

Other observations

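The bound on the microglia score and the test of inner retinal lists against matched random lists were chosen after the results were seen, as were the covariates of total count and pigment epithelium score, the list without Lyz2 and the sets by library number. CNP 12 stood apart from the other libraries in genes of striated muscle: Acta1 measured 58.7 CPM (8.94 in the next highest library), Cox6a2 19.3 (3.03) and Mylpf 70.8 (41.1). The same library held 176 CPM of Xist, the RNA that silences an X chromosome in female cells, against 47.1 in the next highest.

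Whether the 0 genes called could hide a structure of the samples was examined with 100 of the 126 splits of the 10 libraries into 5 and 5. With a real count of 0, all 100 gave as many genes; 3 of the others called any, and the highest called 3768. That split parts the 5 libraries numbered up to 10 from the 5 above 10. With this number as a covariate, edgeR called 0 genes by treatment, with 272 at an unadjusted p under 0.05. The split of the 5 larger from the 5 smaller totals called 772 genes and 18 lists, so the libraries differ among themselves along lines other than treatment. The treatment split had 137 genes at an unadjusted p under 0.05, while the median of the others was 311 and 12 others had as few. Camera called 5 lists in the treatment split, and 74 of 100 splits called as many (highest 18, median 8 in the others), so chance cannot be excluded for the number of lists called.

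The lean of the activated phagocyte list (score difference 0.356) was weighed against 3 technical or compositional explanations. A rise of microglia as a whole stays open: the microglia score differed by 0.0868 (exact permutation p = 0.556), the same test leaves open a shift of up to 0.409, and without CNP 20 camera called that list higher (adjusted p = 0.00491, but adjusted p = 0.903 with an estimated correlation). With the pigment epithelium score as a covariate the mean log2 CPM difference was 0.413 (camera adjusted p = 0.000813, unadjusted estimated-correlation p = 0.0585 against 0.0207 without it). The difference did not fall, which argues against that layer, as far as its score measures it, as the whole cause. The score does not measure other cells carried over with the retina. With log2 total count as a covariate the difference was 0.362 (camera adjusted p = 0.00115, unadjusted estimated-correlation p = 0.0305). Mean totals were close in the groups (4468000 in PBS and 4396000 in CNP), so this covariate could hardly lower the difference and decides nothing on depth. Only 2 of 100 splits gave this list a camera p as small (4.73e-06, best other 3.42e-06), but 70 of 100 gave a p as small to some list, and this one was picked from 33, so chance stays open. Without Lyz2 the mean difference was 0.278 (adjusted p = 0.00295, unadjusted estimated-correlation p = 0.0604), and an effect of the treatment stays open.

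The first principal component followed the total count, and 3 explanations were weighed. Counting depth itself is argued against, because after every library was thinned to the smallest total (3328518) the correlation with the original total was -0.856; the relation was weaker within the sets by library number (r = -0.527, exact permutation p = 0.146), so what the number marks stays open beside what made the totals differ, such as RNA input. Loading on the component went with transcript length across genes (Spearman rho = -0.303 over 11347 genes, which are not independent replicates), just past the bound of -0.3 set beforehand, so RNA integrity or length bias stays open. The bipolar, amacrine and ganglion cell lists lay at percentile 0 of 10000 random lists matched on length and expression. Müller glia lay at 0.03, cones at 88.6 and rods at 100. Lists not tied to a cell type followed the component too, such as circadian clock (r = -0.958), heat shock (-0.946) and ribosomal proteins (0.937). Against random lists of unrelated genes, any list whose genes vary together can look extreme. A varying share of inner retina may contribute, but these values do not single it out. The component showed no difference between the groups (exact permutation p = 0.81). With 5 libraries in each and a wide spread, this does not exclude a contribution of the treatment.

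Of 15 mitochondrial genes searched, 5 had 0 counts in every library (mt-Co2, mt-Co3, mt-Atp6, mt-Atp8 and mt-Nd4l), while their neighbours were counted (mt-Co1 41759, mt-Nd4 87769). If reads shared with nuclear copies were not counted, these genes should match other transcripts. For 4 of the 5, between 98.7% and 99.9% of windows of 75 bases occurred in an annotated nuclear pseudogene, but the lowest was 0% for mt-Atp8, and mt-Nd3 was 97.8% shared yet had 6518 counts. The search covered annotated transcripts only, so a nuclear copy of mt-Atp8 outside them was not searched, and the explanation could not be decided. No biological explanation was tested; the zeros lie in both groups alike.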
